A study of Homo sapiens with 50 samples.

How the data were processed

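The values are those of 50 Affymetrix HG-U219 arrays of biotin-labelled total RNA from A549 cells, extracted with Trizol per the labels' protocols. The deposited table holds log2 probe set signals that the authors made with RMA, which corrects background, normalizes between arrays and summarizes probes; RMA and limma are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. Such summaries compress changes of dim probe sets, and a normalization between arrays removes any shift shared by all genes. No background or detection value was used here, so the lowest signals have no stated floor. Every one of the 50 columns was matched to its sample by accession and title, and 0 columns were without a sample. No 2 arrays held identical values.

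The table has 49386 probe sets. By the platform annotation, 45311 name 1 gene symbol, 1269 several and 2713 none, and 93 are Affymetrix controls. That annotation can be old, so 56 symbols were updated through the RefSeq gene table of assembly GRCh38.p14, which was used for names alone. Probe sets with several symbols or none were left out of the gene tests. Where several probe sets name a gene (11843 of 18227 genes), the probe set with the highest mean over all arrays stood for it. Values were used as deposited, with no further normalization and no filter.

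All 50 arrays entered 1 limma fit (limma 3.58.1, R 4.3.3) of 17 group means, with eBayes moderation (33 residual and 3.7 prior degrees of freedom), so that small groups share 1 estimate of the spread. There were 18 comparisons: compound 16 against DMSO in each medium at each of 4 times, the difference of these effects between media at each time, medium without against medium with serine in DMSO at each time, and each medium at 0 h in DMSO against the cells before the change of medium. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The median SE was 0.122 on the log2 scale, 0.137 for comparisons of 3 with 2 arrays, 0.173 for the difference between media and 0.183 for that difference at 1.5 h. The number of arrays limits the precision. The labels do not say whether arrays of a group came from separate cultures. The p-values of genes therefore measure the spread between these arrays, which may be technical. Numbers at the end of the titles run through the series, no groups share them and they pair no samples. They lie in blocks by time, with the cells before the change of medium in a block of their own, so any shift between these blocks coincides with time and with the change of medium. A shift shared by all arrays of a time cancels within it. Within a time the numbers also run group by group, so a drift in their order would coincide with medium and compound.

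A set of 26 gene lists with 440 members, of which 411 were measured, was fixed before the data were examined. Each was tested with camera at a preset correlation between genes of 0.01, with adjustment over the 26 lists of a comparison. A camera p compares a list with the other genes at that preset, so it does not measure the spread between arrays alone. Estimating the correlation can raise it by far. For the amino acid response, serine lack at 6 h minus that at 0 h, the camera adjusted p went from 1.43e-41 to 7.26e-14. Of the 468 list tests 125 were called, and 13 of these calls were lost when the correlation was estimated; each is given in the report beside that p, and the other calls held. Counts adjusted over the list alone used the same p-values. Named genes followed a rule fixed before the data were examined: PKM, PHGDH, PSAT1, PSPH, SHMT2, MTHFD2, ASNS and TXNIP always; up to 10 genes with the largest rise and up to 10 with the largest fall per comparison among called genes whose arrays did not overlap between groups (up to 5 each way at 0 h and 1.5 h and for differences between media, the latter without the overlap condition); and the 3 members with the smallest p of each called list. Loci named by number were skipped. For 3 against 3 arrays, chance alone gives no overlap in 10% of genes.

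The fit was tested on simulated arrays with 100 genes changed by each of 2 sizes. The aminoacyl-tRNA synthetases were raised by 0.3 in them to test camera, and calls among these are in neither of the counts that follow. Noise was drawn independently for each gene with the same spread in all groups. Recovery where fewer genes change may be lower. For compound 16 without serine at 24 h, 72% of changes of 0.5 and 99% of changes of 1 on the log2 scale were recovered among 18227 genes, with 8 unchanged genes called. For the difference between media at 24 h, 24% and 89% were recovered with 5 unchanged genes called, for serine lack at 6 h 65% and 100% with 13, and for the change of medium with serine 61% and 95% with 6.

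Alternatives set before the data were examined were: leaving out genes under the 40th percentile of mean signal, quantile normalization, centring each array on its median, a trended robust prior, array weights, a fit of only the arrays of the comparison, the mean of all probe sets of a gene, leaving out each array in turn and, for lists, camera with an estimated correlation and fry. The fit of only the arrays of the comparison and the leave-outs were set for genes and counts of genes, not for lists. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3. Differences between times and the leave-out check of the interferon list were added after the data were seen.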

Results

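Transcript levels were measured in A549 cells, a human lung adenocarcinoma line, on 50 Affymetrix HG-U219 arrays that form 17 groups. Cells growing in RPMI medium were sampled before a change of medium. The others were moved to basal medium with non-essential amino acids, made with or without serine, 24 h before 1 uM compound 16 or DMSO was added. They were collected 0, 1.5, 6 and 24 h after the addition. The title of the series names a small molecule that activates PKM, the pyruvate kinase of the last step of glycolysis, and a need for external serine. Each group held 3 arrays, apart from the DMSO group with serine at 1.5 h, which held 2. The deposited log2 signals ran from 3.36 to 14.6, and the array medians lay between 5.40 and 5.54. Within groups, the SD over genes of the difference between 2 arrays was 0.194 to 0.255. The 3′ minus 5′ signal of ACTB, a sign of RNA integrity, had group means between 1.01 and 1.37 on the log2 scale, and that of GAPDH lay between -0.19 and -0.12. Of the 18227 genes tested, each is given as a log2 difference ± SE from the limma fit, with n = 3 arrays per group unless stated.

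The comparison of compound 16 with DMSO in medium without serine asked how cells that lack external serine respond to the compound. At 1.5 h, DDIT3, a transcription factor of the integrated stress response, rose by 1.19 ± 0.19 (adjusted p = 0.00146). GDF15, a stress-induced cytokine, rose by 0.66 ± 0.07, TSC22D3 by 0.71 ± 0.08, ATF3 by 0.67 ± 0.14 and JUN by 0.70 ± 0.15. In all, 14 genes rose and 1, FAM98A, fell, by 0.26 on the log2 scale. Among 19 measured genes of the amino acid response, which the transcription factor ATF4 drives, 3 rose (13 adjusted over the list alone), with DDIT4 at 0.47 ± 0.07. The list median was 0.31 (camera adjusted p = 5.3e-25). Immediate early genes had a median of 0.24 (camera adjusted p = 5.49e-15), with KLF2 and JUN of 18 past the test (8 adjusted over the list alone). The serine synthesis enzymes had not passed the test at this time, with PHGDH at 0.02 ± 0.08 and PSAT1 at -0.05 ± 0.08. The count of 15 was 0 when only the 6 arrays of the comparison were fitted, and 6 to 8 when any of these arrays was left out.

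At 6 h without serine, genes of the amino acid response rose nearly as a block. TRIB3, a pseudokinase induced by ATF4, rose by 1.85 ± 0.07 (3.61-fold, adjusted p = 9.99e-21), DDIT3 by 1.91 ± 0.19, STC2 by 1.71 ± 0.17, PCK2 by 1.31 ± 0.09 and ASNS, the asparagine synthetase, by 0.88 ± 0.07. Of the 19 members, 17 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 1.32e-73). PHGDH, PSAT1 and PSPH, which make serine from a glycolytic intermediate, rose by 0.63 ± 0.08, 0.60 ± 0.08 and 0.55 ± 0.06. MTHFD2 and SHMT2, mitochondrial enzymes of one-carbon metabolism, rose by 0.61 ± 0.06 and 0.48 ± 0.07, while their list of 19 one-carbon and glycine genes did not pass (4 higher, 4 and 2 lower adjusted over the list alone; camera adjusted p = 0.0535). The median of that list was -0.06 and its mean 0.09. PKM itself stood at -0.07 ± 0.07 (adjusted p = 0.784). Its probe sets were not matched to its splice forms here.

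Other groups moved with them at 6 h. Of 19 aminoacyl-tRNA synthetases 11 rose (12 adjusted over the list alone, with 1 lower), with CARS1 at 0.75 ± 0.06, and of 19 amino acid transporters 8 rose (10 adjusted over the list alone), among them SLC7A1 at 0.67 ± 0.06. Of 19 cholesterol synthesis genes 8 fell (11 adjusted over the list alone; camera adjusted p = 2.82e-16): INSIG1, a sterol-regulated target, by -1.13 ± 0.08, and HMGCS1 by -0.69 ± 0.11. Fatty acid synthesis had a median of -0.13, with ELOVL6 of 12 genes past the test (1 higher and 4 lower adjusted over the list alone). Among 23 S phase genes 8 fell (13 adjusted over the list alone), with FEN1 at -0.52 ± 0.08, and among 23 mitosis genes 4 fell (13 adjusted over the list alone), with CDC20 at -0.27 ± 0.06. TXNIP, an arrestin whose transcription responds to sugar phosphates, rose by 0.95 ± 0.23 (adjusted p = 0.0129). The heat shock genes HSPA2 and HSPA1B fell by -0.86 ± 0.07 and -0.75 ± 0.06, and the chemokine gene CCL2 by -1.09 ± 0.22. NIBAN1, NUPR1, CHAC1, SESN2, SCG5 and ULBP1 rose by 1.25 to 1.60, and FGFBP1, EGLN3, EDN2, FAM111B, NPAT and SKP2 fell by -1.04 to -0.71. Of p53 targets, GDF15 rose by 0.91 ± 0.07, and 3 of 19 rose and 1 fell (4 and 1 adjusted over the list alone). Autophagy and lysosome genes had a median of 0.08, with MAP1LC3B at 0.41 ± 0.07 and 2 of 22 past the test by either adjustment. The 18 immediate early genes had a median of 0.17 (camera adjusted p = 0.00224, and adjusted p = 0.076 with an estimated correlation).

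In all, 271 genes rose and 225 fell at 6 h without serine, 18 of them at least 2-fold. The count of 496 was 89 when only the 6 arrays of the comparison were fitted, 768 with array weights, 307 without minusSer_6h_C16 replicate 63 and 328 without minusSer_6h_C16 replicate 64. With arrays centred on their medians 224 rose and 259 fell.

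At 24 h without serine, NIBAN1, a stress-induced regulator of translation, rose by 3.35 ± 0.16 (10.2-fold), and STC2 by 2.73 ± 0.17 (6.62-fold). BCAT1, the cytosolic branched-chain aminotransferase, rose by 2.33 ± 0.17, NUPR1 by 2.30 ± 0.12, CBS, which condenses serine with homocysteine, by 2.08 ± 0.08 and BEX2 by 1.74 ± 0.12. PHGDH rose by 1.60 ± 0.08 (3.04-fold, adjusted p = 9.05e-18), PSAT1 by 1.32 ± 0.08, PSPH by 0.51 ± 0.06, MTHFD2 by 1.08 ± 0.06, SHMT2 by 0.61 ± 0.07 and ASNS by 1.90 ± 0.07. PKM fell by -0.35 ± 0.07 (adjusted p = 0.000226). The level of ASNS under the compound was 12.79 ± 0.01 (SD, n = 3) at 6 h and 12.68 ± 0.04 at 24 h, while in DMSO it was 11.91 ± 0.05 and 10.78 ± 0.07.

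Of the 19 amino acid response genes 16 rose at 24 h (17 adjusted over the list alone; median 0.95, camera adjusted p = 1.06e-49). Of the aminoacyl-tRNA synthetases 12 rose (14 adjusted over the list alone), with MARS1 at 1.29 ± 0.07 and SARS1, which charges serine, at 1.11 ± 0.07. Of the amino acid transporters 8 rose and 2 fell (9 and 2 adjusted over the list alone), with SLC1A4, a carrier of alanine, serine and cysteine, at 1.33 ± 0.09. Among 19 one-carbon and glycine genes 4 rose and 2 fell (5 and 3 adjusted over the list alone). Both ARRDC4 (0.74 ± 0.11) and TXNIP (0.93 ± 0.23) rose.

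All 23 mitosis genes fell at 24 h without serine, by either adjustment, with a median of -0.64 (camera adjusted p = 1.49e-62). The mean signal of the list under the compound was 9.854 at 6 h and 9.712 at 24 h, while in DMSO it was 10.016 and 10.372. The difference at 24 h was thus formed with a higher DMSO level than at 6 h. KIF20A, a kinesin of cytokinesis, fell by -0.98 ± 0.07, KIF11 by -0.76 ± 0.06 and SGO2, a protector of centromeric cohesion, by -1.12 ± 0.09. Of the S phase genes 8 fell (13 adjusted over the list alone), with RRM2 at -0.60 ± 0.06. Cholesterol synthesis fell in 17 of 19 genes (18 adjusted over the list alone; median -0.81, camera adjusted p = 8.22e-44), with ACAT2 at -1.12 ± 0.06, DHCR7 at -1.16 ± 0.10 and SQLE at -0.98 ± 0.06. Fatty acid synthesis fell in 8 of 12 genes (9 adjusted over the list alone), with FADS2 at -1.12 ± 0.13 and SCD at -0.42 ± 0.05. FGFBP1 fell by -2.12 ± 0.15, NR4A1 by -1.31 ± 0.10 and ALDOC, an aldolase, by -1.19 ± 0.16.

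Smaller shifts at 24 h without serine were these. Of 19 interferon-stimulated genes 4 fell (5 adjusted over the list alone; camera adjusted p = 0.00131), with OAS1 at -1.10 ± 0.08. Of p53 targets 6 rose (7 adjusted over the list alone), with CDKN1A at 0.31 ± 0.07. Of 19 ribosome biogenesis genes 3 rose by either adjustment, with RRP12 at 0.38 ± 0.08. Of autophagy and lysosome genes 3 rose and 1 fell by either adjustment, with SQSTM1 at 0.18 ± 0.05 and GLA at -0.26 ± 0.05. Lists whose call was lost were glycolysis (median -0.09, 1 of 19 higher and 4 lower, 1 and 6 adjusted over the list alone, adjusted p = 0.131 with an estimated correlation), NRF2 targets (median 0.01, 4 of 17 higher, 5 adjusted over the list alone, adjusted p = 0.128 with an estimated correlation) and the ER unfolded protein response (median 0.08, 6 of 18 higher and 2 lower, 8 and 2 adjusted over the list alone, adjusted p = 0.0846 with an estimated correlation). In the last of these, HERPUD1 rose by 0.75 ± 0.07 and the chaperone gene CALR fell by -0.62 ± 0.09. In all, 542 genes rose and 748 fell, 50 of them at least 2-fold. The count of 1290 was 440 with only the 6 arrays of the comparison, and with arrays centred on their medians 691 rose and 594 fell.

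At 0 h without serine, when the cells had had no time with the compound, limma called 0 genes. At an unadjusted p under 0.05 there were 1317, and the smallest adjusted p was 0.177. With no change in any gene, a share of 0.05 of the 18227 genes is expected at that level, and 1317 lies above it. The cause of this excess was not tested. Without minusSer_0h_C16 replicate 17 the count was 6, without minusSer_0h_DMSO replicate 19 it was 2, and with the mean of all probe sets it was 1.

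**Figure D1:**
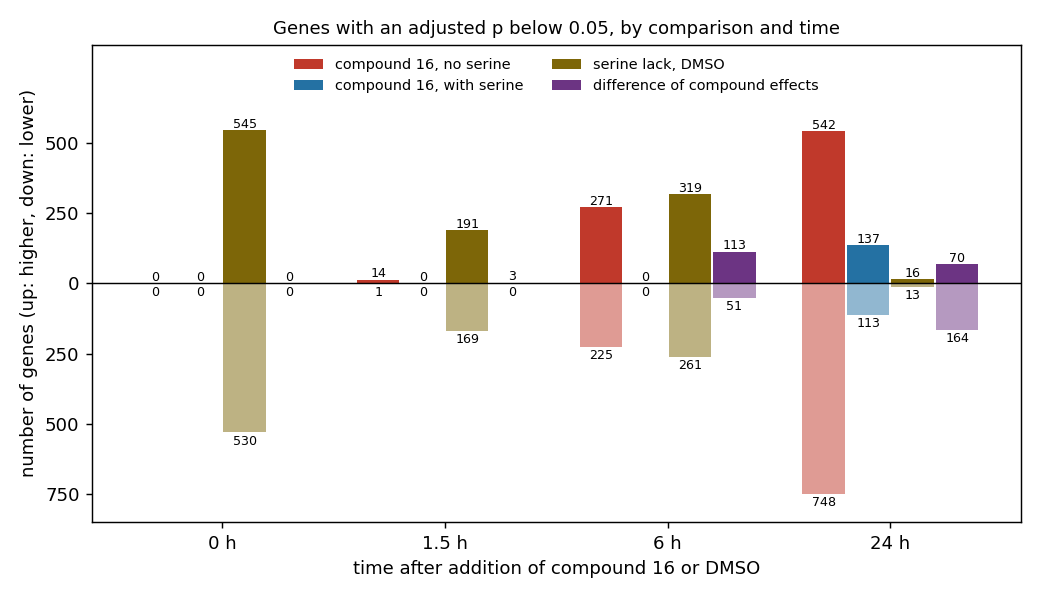
Number of genes with an adjusted p below 0.05 (vertical axis, genes higher above 0 and lower below 0) for 4 kinds of comparison at each time after addition (horizontal axis, h); bars carry their counts. Compound 16 without serine called 15 genes at 1.5 h and 1290 at 24 h, and with serine it called 250 at 24 h.

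The same comparison with serine in the medium asked what the compound does when serine is supplied. At 24 h, PHGDH rose by 1.45 ± 0.08 (2.74-fold, adjusted p = 4.59e-16), PSAT1 by 0.82 ± 0.08, PSPH by 0.36 ± 0.06, MTHFD2 by 0.89 ± 0.06, SHMT2 by 0.52 ± 0.07 and ASNS by 1.35 ± 0.07. STC2, NIBAN1, NUPR1, PCK2, CBS, TRIB3 and BCAT1 rose by 1.32 to 1.89. FGFBP1 fell by -0.84 ± 0.15, HMGCS1 by -0.67 ± 0.11, IDI1 by -0.62 ± 0.10, SGK1, a serum- and glucocorticoid-induced kinase, by -0.57 ± 0.11, and PC, the pyruvate carboxylase, by -0.53 ± 0.13. PKM stood at -0.10 ± 0.07 (adjusted p = 0.62) and TXNIP at 0.70 ± 0.23 (adjusted p = 0.149).

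By group at 24 h with serine, 13 of 19 amino acid response genes rose (14 adjusted over the list alone; median 0.73, camera adjusted p = 3.37e-57), as did 11 aminoacyl-tRNA synthetases (12 adjusted over the list alone), with GARS1 at 0.70 ± 0.06, and 7 amino acid transporters (9 adjusted over the list alone), with SLC1A5 at 0.67 ± 0.07. Cholesterol synthesis fell in 10 of 19 genes (13 adjusted over the list alone; median -0.35, camera adjusted p = 1.45e-24). Among one-carbon genes 3 rose and 1 fell (3 and 2 adjusted over the list alone). The median was -0.16 for S phase genes, with 3 of 23 lower (13 adjusted over the list alone), and -0.12 for mitosis genes, with 1 of 23, CDC20 at -0.33 ± 0.06, lower (2 adjusted over the list alone). Of 12 fatty acid synthesis genes 0 passed the test (3 lower adjusted over the list alone; camera adjusted p = 0.00137). The p53 list (2 of 19 higher, 5 adjusted over the list alone, with GDF15 at 0.29 ± 0.07), the ER unfolded protein response (2 of 18 higher by either adjustment, with HERPUD1 at 0.50 ± 0.07) and autophagy and lysosome genes (0 of 22 by either adjustment, median 0.08) were shifted upwards, with camera adjusted p = 0.0107, 0.00247 and 0.0122.

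In all, 137 genes rose and 113 fell at 24 h with serine, 15 of them at least 2-fold, and the 15 were all higher. The count of 250 was 24 with only the 6 arrays of the comparison, 391 with dim genes left out, 128 without plusSer_24h_C16 replicate 94 and 139 without plusSer_24h_DMSO replicate 98. With arrays centred on their medians 109 rose and 181 fell.

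At the earlier times with serine, ASNS stood at -0.02 ± 0.07 at 0 h, -0.01 ± 0.07 at 1.5 h (n = 3 and 2) and -0.09 ± 0.07 at 6 h, and PHGDH at -0.25 ± 0.08, 0.01 ± 0.09 and 0.03 ± 0.08. Limma called 0 genes at each of these times, with 1029, 613 and 1102 at an unadjusted p under 0.05. A share of 0.05 of the 18227 genes is expected there with no change at all, and 613 lies below it and the others above. No gene list passed the camera test at any of them. The other settings called at most 2, 1 and 1 genes at 0, 1.5 and 6 h. In simulated data of the 1.5 h design, 97% of changes of 1 on the log2 scale and 52% of changes of 0.5 were recovered. Those data held 100 changed genes of each size and independent noise, so the rates do not give the power where few genes change.

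**Figure D2:**
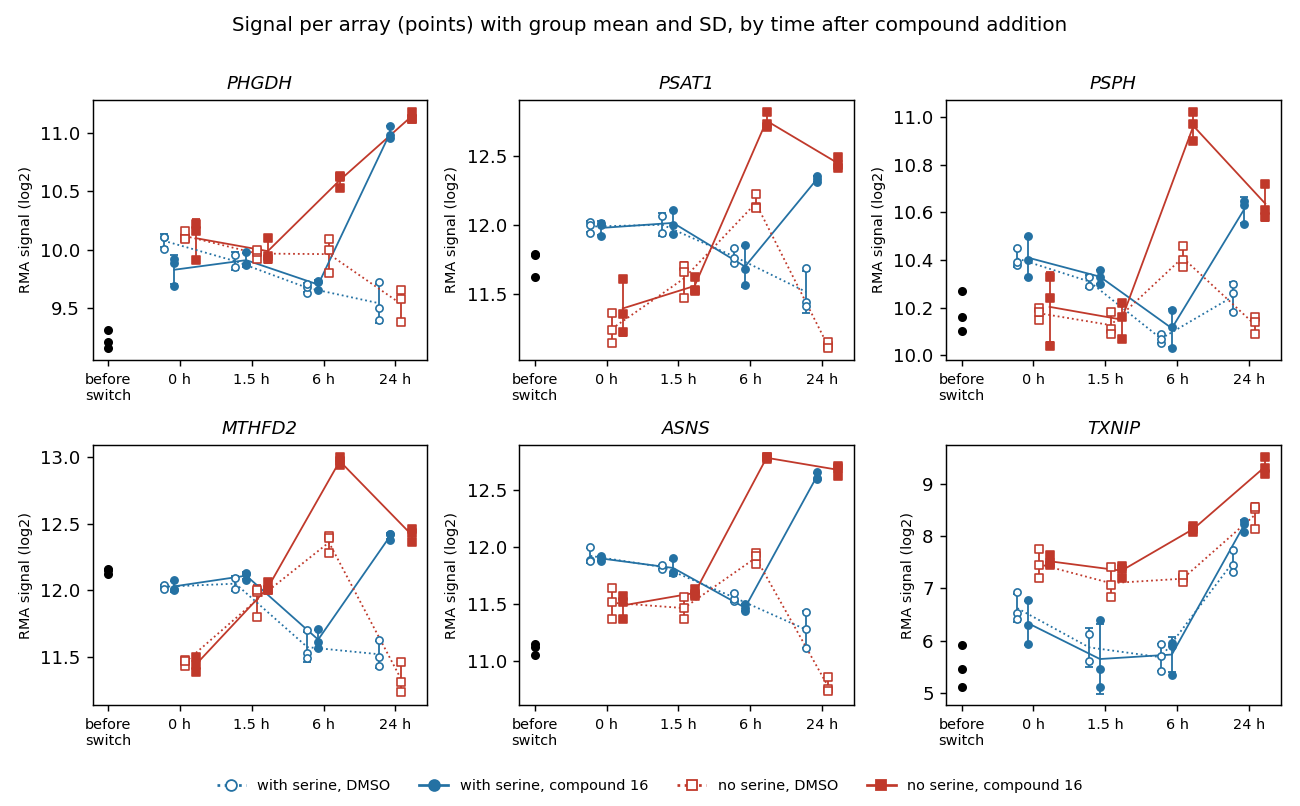
RMA signal on the log2 scale (vertical axes) of 6 genes per array against time after addition (horizontal axis); points are arrays, lines join group means, bars are SDs, and black points are cells before the change of medium. Without serine, PHGDH under compound 16 was 10.59 ± 0.06 at 6 h and 11.14 ± 0.03 at 24 h; with serine it was 9.70 ± 0.04 and 11.00 ± 0.06.

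Whether serine changed the response was tested as the compound's effect without serine minus its effect with serine. At 1.5 h (n = 2 for DMSO with serine and 3 for the other groups) the effects on GDF15, TSC22D3 and DDIT4 differed. The differences were 0.83 ± 0.10, 0.77 ± 0.12 and 0.57 ± 0.11. The amino acid response list differed by a median of 0.31 (camera adjusted p = 2.94e-12; 1 of 19 genes past the test, 7 adjusted over the list alone), and the immediate early genes by 0.30 (camera adjusted p = 5.24e-13; 0 of 18 past the test, 6 adjusted over the list alone). These were the 3 genes called, a count that was 7 with dim genes left out, 8 with a trended robust prior, 13 with array weights, 0 with only the arrays of the comparison and 1 without plusSer_1.5h_DMSO replicate 49.

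At 6 h the compound acted on the amino acid response almost solely without serine. Its effect on TRIB3 differed by 1.73 ± 0.10, on NIBAN1 by 2.01 ± 0.23, on DDIT3 by 1.82 ± 0.28, on ASNS by 0.97 ± 0.09, on PSAT1 by 0.67 ± 0.11 and on PHGDH by 0.60 ± 0.11 (adjusted p = 0.00192). Of the 19 amino acid response genes 15 differed (18 adjusted over the list alone; median 0.93, camera adjusted p = 1.74e-63), as did all 3 serine synthesis genes, 10 of 19 aminoacyl-tRNA synthetases (12 higher and 1 lower adjusted over the list alone) and 6 of 19 transporters (9 adjusted over the list alone). INSIG1 differed by -0.98 ± 0.12, and 6 cholesterol synthesis genes had a more negative effect without serine (8 adjusted over the list alone). Of S phase genes 2 differed (7 adjusted over the list alone), and of mitosis genes 0 by either adjustment (median -0.09, camera adjusted p = 0.00103). The immediate early list had adjusted p = 0.114 with an estimated correlation (median 0.15, 0 of 18 past the test, 2 and 1 adjusted over the list alone). In all, 113 genes had a more positive and 51 a more negative effect without serine, and the count of 164 was 56 with only the 12 arrays of the comparison.

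By 24 h the serine synthesis enzymes responded in both media, and the clearest differences lay elsewhere. The effect on PHGDH differed by 0.15 ± 0.11 (adjusted p = 0.704), on PSAT1 by 0.50 ± 0.11 (adjusted p = 0.0137) and on ASNS by 0.55 ± 0.09. Under the compound, the ASNS arrays lay at 12.63 to 12.71 without and 12.6 to 12.66 with serine. In DMSO they lay at 10.73 to 10.86 and 11.11 to 11.43. For PSAT1 the arrays under the compound lay at 12.41 to 12.49 and 12.31 to 12.35, and those in DMSO at 11.11 to 11.15 and 11.41 to 11.69. Of the 23 mitosis genes, 21 had a more negative effect without serine (22 adjusted over the list alone; median -0.56, camera adjusted p = 2.13e-54), with KIF20A at -0.82 ± 0.09 and AURKA at -0.66 ± 0.09. Of the cholesterol synthesis genes 7 did (13 adjusted over the list alone), with ACAT2 at -0.64 ± 0.08, and of the fatty acid synthesis genes 3 (5 adjusted over the list alone), with SCD at -0.35 ± 0.06. Aminoacyl-tRNA synthetases had a more positive effect without serine in 7 of 19 genes (11 adjusted over the list alone), with WARS1 at 0.55 ± 0.08. Amino acid response genes did in 2 of 19 (9 adjusted over the list alone; median 0.23). The mean signal of that list under the compound was 9.071 without and 9 with serine. In DMSO it was 8.027 and 8.202. The difference for this list thus lay more in the DMSO level than in the level under the compound.

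IFIT1, an interferon-induced gene, was 7.54 ± 0.16 (SD, n = 3) under the compound and 6.82 ± 0.31 in DMSO with serine, against 6.21 ± 0.16 and 6.80 ± 0.31 without serine. Its difference was -1.30 ± 0.25 (adjusted p = 0.00211), and 4 of the 19 interferon-stimulated genes had a more negative effect without serine (8 adjusted over the list alone; camera adjusted p = 1.69e-06). ALDOC differed by -1.29 ± 0.22. In all, 70 genes had a more positive and 164 a more negative effect without serine. The count of 234 was 67 with only the 12 arrays of the comparison, and with arrays centred on their medians it was 203, of which 101 were more positive. At 0 h limma called 0 genes for the difference (1071 at an unadjusted p under 0.05, and 1 with arrays centred on their medians).

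The calls of both media at 24 h overlapped. Of the genes that rose, 98 were called in both, where independent lists of these sizes would share 4.07, and of those that fell 84, against 4.64. These comparisons shared no arrays, but 1 fit gave both the same spread per gene, so genes of small spread tend to be called in both. The numbers for independent lists may thus be too low. Of the genes that rose without serine 1 was called lower with it, and of those that fell 1 was called higher. Over all genes, which are not independent replicates, Pearson's r between the effects was 0.289. Of the 1290 genes called without serine, 1049 had the same sign with serine.

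**Figure D3:**
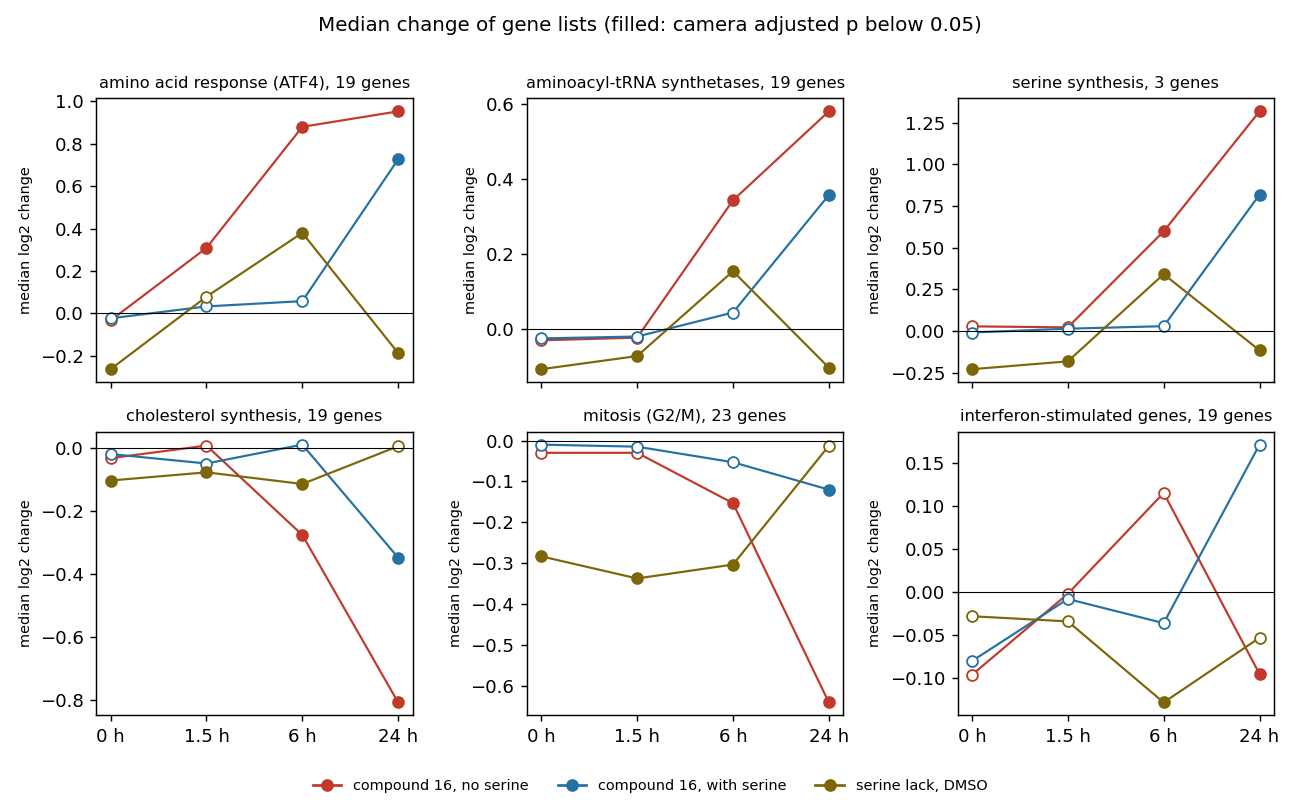
Median log2 change of 6 gene lists (vertical axes) against time after addition (horizontal axis) for compound 16 against DMSO without serine (red) and with serine (blue) and for serine lack in DMSO (brown); filled points passed the camera test. Mitosis genes reached -0.64 at 24 h under the compound without serine and -0.12 with serine.

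The effect of serine itself was read from the DMSO arrays, as medium without serine minus medium with serine. At 0 h, which was 24 h after the change of medium, PSAT1 was lower without serine by -0.74 ± 0.08 (adjusted p = 1.25e-07), MTHFD2 by -0.57 ± 0.06, ASNS by -0.41 ± 0.07, STC2 by -1.18 ± 0.17 and CBS by -0.69 ± 0.08. TXNIP was higher by 0.84 ± 0.23, and PHGDH stood at 0.04 ± 0.08 (adjusted p = 0.839). FCGBP, SRPX2, TPPP3, AGTR1 and CSTA were higher by 0.93 to 1.11, and GLI1, SLCO2B1 and NPTX1 lower by -1.19 to -1.02. Of the amino acid response genes 10 of 19 were lower (11 adjusted over the list alone; median -0.26, camera adjusted p = 1.17e-11), as were 6 transporters, with 1 higher (6 and 2 adjusted over the list alone), 7 aminoacyl-tRNA synthetases (7 and 1 adjusted over the list alone) and 5 one-carbon genes, with 1 higher (5 and 2 adjusted over the list alone). Mitosis genes were lower in 18 of 23 (20 adjusted over the list alone; median -0.28, camera adjusted p = 4.59e-25), with NUSAP1 at -0.58 ± 0.08, and S phase genes in 7 of 23 (8 adjusted over the list alone). Cholesterol synthesis was lower in 4 genes and higher in 1 (5 and 1 adjusted over the list alone). The ER unfolded protein response was higher in 5 of 18 genes and lower in 1 (7 and 1 adjusted over the list alone), with HYOU1 at 0.46 ± 0.07. In all, 545 genes were higher and 530 lower, and the count of 1075 was 6 with only the 6 arrays of the comparison. After quantile normalization 552 were higher and 614 lower, and with arrays centred on their medians 580 and 435.

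At 1.5 h (n = 3 without and 2 with serine), DDIT3 was higher without serine by 1.28 ± 0.22, CHAC1 by 1.26 ± 0.18, TXNIP by 1.23 ± 0.26 and BBC3, a p53 target that promotes apoptosis, by 0.75 ± 0.08, while CYP1B1 and TIPARP, targets of the aryl hydrocarbon receptor, were lower by -0.90 ± 0.09 and -0.89 ± 0.10. PSAT1 was lower by -0.39 ± 0.09 and ASNS by -0.36 ± 0.07. The amino acid response list did not pass at this time, with 4 of 19 genes higher and 2 lower (7 and 3 adjusted over the list alone; median 0.08, camera adjusted p = 0.0685). Mitosis genes were lower in 18 of 23 (23 adjusted over the list alone; median -0.34). S phase genes were lower in 1 of 23 (10 adjusted over the list alone; camera adjusted p = 3.52e-10), aminoacyl-tRNA synthetases in 5 of 19 (7 adjusted over the list alone), cholesterol synthesis in 3 (4 adjusted over the list alone) and one-carbon genes in 2 (3 adjusted over the list alone). The p53 list was higher in 3 of 19 (4 adjusted over the list alone) and the ER unfolded protein response in 3 of 18 (7 adjusted over the list alone), a call that ended with the mean of all probe sets. Transporters had adjusted p = 0.067 with an estimated correlation (median -0.08, 1 of 19 higher and 3 lower, 2 and 5 adjusted over the list alone), and glycolysis adjusted p = 0.149 with an estimated correlation (median -0.06, 2 of 19 lower by either adjustment). In all, 360 genes differed, 169 of them lower. The count was 1 with only the 5 arrays of the comparison, 631 with array weights, 85 without plusSer_1.5h_DMSO replicate 49, 101 without plusSer_1.5h_DMSO replicate 50, 189 without minusSer_1.5h_DMSO replicate 54 and 233 without minusSer_1.5h_DMSO replicate 56. With arrays centred on their medians, 85 were higher and 387 lower, and after quantile normalization 164 and 172.

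At 6 h the amino acid response stood on the other side. STC2 was higher without serine by 1.97 ± 0.17, TXNIP by 1.50 ± 0.23, TRIB3 by 1.05 ± 0.07, MTHFD2 by 0.79 ± 0.06 and ATF4 by 0.53 ± 0.05. PSAT1, PSPH, ASNS and PHGDH were higher by 0.39 ± 0.08, 0.34 ± 0.06, 0.35 ± 0.07 and 0.29 ± 0.08. Of the 19 amino acid response genes 10 were higher (13 adjusted over the list alone; median 0.38, camera adjusted p = 5.7e-26), as were 8 aminoacyl-tRNA synthetases (8, with 1 lower, adjusted over the list alone), 5 transporters (6 adjusted over the list alone) and 2 of 22 autophagy and lysosome genes (4 adjusted over the list alone). CEMIP, SLITRK6, GASK1B and LYZ were higher by 1.08 to 1.36, and MYOCD, CTSV, HAS3 and SERPINH1, a collagen chaperone gene, lower by -0.80 to -0.62. Mitosis genes were lower in 18 of 23 (23 adjusted over the list alone; median -0.30) and S phase genes in 5 (14 adjusted over the list alone). Cholesterol synthesis genes were lower in 3 by either adjustment, and interferon-stimulated genes in 3 (4 adjusted over the list alone), with OAS1 at -0.63 ± 0.08. Ribosome biogenesis had a median of -0.05, with 0 of 19 past the test by either adjustment (camera adjusted p = 0.042), a call that ended under quantile normalization and with dim genes left out. Calls lost with an estimated correlation were those of glycolysis (2 of 19 lower by either adjustment, adjusted p = 0.0757 with an estimated correlation), p53 targets (2 of 19 higher, 5 adjusted over the list alone, adjusted p = 0.0583 with an estimated correlation) and the ER unfolded protein response (2 of 18 higher, 3 adjusted over the list alone, adjusted p = 0.0757 with an estimated correlation). In all, 319 genes were higher and 261 lower. The count of 580 was 25 with only the 6 arrays of the comparison, 305 without plusSer_6h_DMSO replicate 62, 355 without minusSer_6h_DMSO replicate 67 and 366 without minusSer_6h_DMSO replicate 66; with arrays centred on their medians 243 were higher and 324 lower.

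At 24 h few genes separated the media. CEMIP was higher without serine by 1.01 ± 0.14, FCGBP by 0.80 ± 0.11 and IGFBP1 by 0.67 ± 0.12, and NUPR1 was lower by -0.79 ± 0.12, CBS by -0.77 ± 0.08, ASNS by -0.49 ± 0.07 and PSAT1 by -0.39 ± 0.08. Amino acid response genes were lower in 3 of 19 (4 adjusted over the list alone; median -0.19, camera adjusted p = 1.15e-07), aminoacyl-tRNA synthetases in 3 of 19 (8 adjusted over the list alone) and serine synthesis in 1 of 3 by either adjustment. TXNIP was at 0.90 ± 0.23 (adjusted p = 0.109). In all, 16 genes were higher and 13 lower. The count of 29 was 0 with only the 6 arrays of the comparison and 9 to 41 when 1 array was left out; 8 were higher and 19 lower with arrays centred on their medians, and 9 and 14 after quantile normalization. At both 0 h and 1.5 h serine synthesis was also lower, in 2 and 1 of 3 genes (2 and 2 adjusted over the list alone). Of the 3 glucose-sensing genes TXNIP, ARRDC4 and KLF10, 2 were higher at 1.5 h by either adjustment and 1 at 6 h (2 adjusted over the list alone), with camera adjusted p = 0.000308 and 0.00338. For compound 16 without serine this list was higher in 1 gene at 6 h (2 adjusted over the list alone) and 2 at 24 h by either adjustment.

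The change of medium itself was compared as the DMSO arrays at 0 h against the cells before it. With serine, EGR1, an immediate early transcription factor, fell by -5.90 ± 0.21, FOS by -3.46 ± 0.14, NR4A1 by -3.62 ± 0.10, ATF3 by -3.41 ± 0.14 and the chemokine gene CXCL8 by -3.32 ± 0.20. All 18 immediate early genes fell in both media by either adjustment, with medians of -1.73 and -1.79. Cholesterol synthesis rose in 18 of 19 genes with serine and fell in 1, by either adjustment (median 0.80, camera adjusted p = 1.42e-26), and in 17 without serine, where 1 fell (18 and 1 adjusted over the list alone). MSMO1 rose by 1.65 ± 0.08 and 1.52 ± 0.08. Fatty acid synthesis rose in 11 and 9 of 12 genes by either adjustment, with SCD at 1.16 ± 0.05 and 1.05 ± 0.05. The mucosal and secretory genes FCGBP, MUC5B and AGR3 rose by 2.24 ± 0.11, 1.83 ± 0.17 and 1.97 ± 0.23 without serine, and ceruloplasmin, CP, by 2.44 ± 0.14 without and 1.62 ± 0.14 with it.

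PHGDH rose with the change of medium by 0.85 ± 0.08 with and 0.89 ± 0.08 without serine, and TXNIP by 1.12 ± 0.23 and 1.97 ± 0.23, whereas PSAT1 rose by 0.26 ± 0.08 with serine and fell by -0.48 ± 0.08 without it. Serine synthesis rose in 3 of 3 genes with serine by either adjustment. Among amino acid response genes without serine 4 rose and 6 fell by either adjustment; those with the smallest p, ATF3, PPP1R15A and GADD45A, fell by -4.01 ± 0.14, -1.79 ± 0.14 and -0.74 ± 0.07. The list's call (camera adjusted p = 0.0271) ended with dim genes left out. S phase genes fell in 17 of 23 with serine (18 adjusted over the list alone) and 20 without (21 adjusted over the list alone), mitosis genes in 10 (13 adjusted over the list alone) and 23 (23 by either adjustment), and ribosome biogenesis genes in 13 of 19 in both (15 and 14 adjusted over the list alone), with NIP7 at -0.57 ± 0.05 and -0.51 ± 0.05. Of 14 hypoxia genes 5 and 6 fell (7 and 6 adjusted over the list alone), with BHLHE40 at -1.93 ± 0.09 and -1.75 ± 0.09. Autophagy and lysosome genes rose in 11 of 22 in both, with 1 lower without serine (12, and 13 with 1 lower, adjusted over the list alone). NEU1, a lysosomal sialidase, rose by 1.02 ± 0.09 and 1.31 ± 0.09.

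Of the interferon-stimulated genes 7 rose with serine (8 adjusted over the list alone), and 5 rose and 1 fell without it by either adjustment; the latter list had adjusted p = 0.119 with an estimated correlation. Of 8 purine synthesis genes 4 fell in both media (6 and 4 adjusted over the list alone), with adjusted p = 0.158 with an estimated correlation without serine. The ER unfolded protein response rose in 6 of 18 genes and fell in 1 with serine (6 and 2 adjusted over the list alone, adjusted p = 0.174 with an estimated correlation, and a median of -0.03 with arrays centred on their medians) and rose in 7 without it by either adjustment, with XBP1 at 0.88 ± 0.09. In all, 2240 genes rose and 1728 fell with serine, and 2922 rose and 2300 fell without it. With arrays centred on their medians these were 1409 and 2714, and 2195 and 3293. The count of 3968 was 2518 with only the 6 arrays of the comparison. The arrays from before the change form a block of their own in the numbering, so a shift between array blocks and the further 24 h of culture coincide with this comparison. The 3′ minus 5′ signal of ACTB was 1.37 ± 0.09 (SD, n = 3) before the change, 1.22 ± 0.15 at 0 h with serine and 1.14 ± 0.09 without it. Both comparisons used the same 3 arrays from before the change, and the difference between them is the serine comparison at 0 h.

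Several lists passed the camera test in none of the 18 comparisons. Their medians ranged from -0.04 to 0.05 for oxidative phosphorylation (21 genes), -0.04 to 0.03 for the tricarboxylic acid cycle (15 genes), -0.07 to 0.04 for the pentose phosphate pathway (8 genes), -0.05 to 0.09 for alveolar and epithelial markers (14 genes), -0.11 to 0.09 for fibroblast markers (10 genes) and -0.08 to 0.04 for leukocyte and endothelial markers (11 genes).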

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

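The tests of a shift by time point, of fresh medium and of precision at 6 h were chosen after the results they concern had been seen. The test of serine running low was set before its main value was seen, but the move of the amino acid response that it also uses had been seen already. The other tests were set before their results were seen.

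Effects of compound 16 that differed between media by the test of the difference were these, each as the effect without serine minus that with serine. At 1.5 h 3 genes differed: GDF15 (0.83), TSC22D3 (0.77) and DDIT4 (0.57). The lists were the amino acid response (median 0.31) and immediate early genes (0.30). At 6 h 164 genes differed, with NIBAN1 (2.01), DDIT3 (1.82), TRIB3 (1.73), NUPR1 (1.51) and SCG5 (1.48) the most positive and FGFBP1 (-1.12), INSIG1 (-0.98), CLDN2 (-0.86), HSPA1B (-0.85) and HSPA2 (-0.80) the most negative. List medians at 6 h were 0.60 for serine synthesis, 0.93 for the amino acid response, 0.28 for amino acid transporters, 0.29 for aminoacyl-tRNA synthetases, 0.36 for glucose-sensing genes (0 of 3 past the test, 2 adjusted over the list alone), 0.069 for p53 targets, 0.15 for immediate early genes (a call lost at adjusted p = 0.114 with an estimated correlation), -0.30 for cholesterol synthesis, -0.10 for fatty acid synthesis, -0.21 for S phase and -0.09 for mitosis.

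At 24 h 234 genes differed between media, with NIBAN1 (1.62), BEX2 (1.03), BCAT1 (1.01), ZNF177 (0.90) and ZNF540 (0.87) the most positive and IFIT1 (-1.30), ALDOC (-1.29), FGFBP1 (-1.28), TCN1 (-1.20) and BCL2L15 (-1.06) the most negative. List medians were 0.15 for serine synthesis, 0.23 for the amino acid response, 0.29 for aminoacyl-tRNA synthetases, -0.36 for cholesterol synthesis, -0.21 for fatty acid synthesis, -0.56 for mitosis, -0.26 for interferon-stimulated genes and 0.10 for ribosome biogenesis.

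For the difference between media, the arrays were split by compound within each medium in 100 ways, the real split included. As many genes as in the real split were found in 7 of the 100 at 6 h (real 164, highest other 261) and in 10 of the 100 at 24 h (real 234, highest other 789), so chance is not excluded by these shares. They are no measure of chance alone, because of a structure of the arrays: each of these splits still parted the arrays of at least 1 medium by compound and so kept the compound's own effect there. The 83 and 81 splits that parted neither medium by compound gave at most 1 and 2 genes. At 0 h all 100 splits gave at least the real count of 0 (highest other 4). Every split reaches a real count of 0, so such a share, here and in the comparisons that follow, was fixed in advance and tests nothing. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05, and each real value is given with the highest other. For compound 16 without serine, 1 of 10 splits gave as many genes at 1.5 h (15 and 1), 6 h (496 and 2) and 24 h (1290 and 1), and 10 of 10 at 0 h (0 and 2). With serine these were 1 of 10 at 24 h (250 and 1), 10 of 10 at 0 h (0 and 3) and 10 of 10 at 6 h (0 and 0). For serine lack they were 1 of 10 at 0 h (1075 and 1), 6 h (580 and 0) and 24 h (29 and 1), and for the change of medium 1 of 10 with serine (3968 and 2) and without it (5222 and 2).

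The first pattern weighed is the amino acid response under serine lack in DMSO, with a median below the arrays with serine at 0 h and 24 h (-0.26 and -0.19) and above them at 6 h (0.38), while at 1.5 h it was 0.08 and the list did not pass (camera adjusted p = 0.0685). A shift shared by all arrays of a time point cancels within a time by construction and gives neither sign; the difference between the effects at 6 h and 0 h, 0.79 (camera adjusted p = 7.26e-14 with an estimated correlation), restates the pattern and adds no separate evidence. Scaling of the arrays turned 0 of 6 signs but moved the median of all genes too little to turn any, which says nothing; a shift common to all genes is argued against by camera, which compares the list with the other genes (adjusted p = 1.17e-11, 5.7e-26 and 1.15e-07 at 0, 6 and 24 h), while a scaling that depends on the signal stays open. Fresh medium given with the compound or DMSO may have contributed: immediate early genes were higher at 1.5 h than at 0 h by a median of 0.281 in DMSO with serine, but a difference between array blocks would give the same, so the possibility stays open. An effect of serine in the medium that changes with time stays open as a hypothesis and was not tested further.

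The second pattern is that compound 16 with serine called 250 genes at 24 h and 0 at 6 h (1102 at an unadjusted p under 0.05 by limma). Too little precision at 6 h is argued against: in the direction of their 24 h change, those 250 genes had a median of 0.39 at 24 h and -0.012 at 6 h, and without serine 0.27 at 6 h. A candidate explanation is that serine ran low in the medium with serine by 24 h. In DMSO with serine, the 1075 genes called for serine lack at 0 h were followed from 6 h to 24 h. They moved by a median of 0.074 in the direction of serine lack (64.3% of them in that direction), against 0.017 (53%) in DMSO without serine. The amino acid response moved by 0.05. That list was lower without serine at 0 h and higher at 6 h, so its move has no agreed direction and weighs neither way. The test also compares array blocks, and it leaves the explanation open. A slow effect of the compound that needs no loss of serine was not tested.

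The third pattern is the interferon-stimulated genes, whose effects at 24 h differed by a median of -0.26. By sign alone, 14 of 19 had a more negative effect without serine, a count that includes genes not past the test. The sign did not depend on 1 array: the median stayed between -0.333 and -0.203 with each of the 12 arrays left out. The highest camera adjusted p was then 0.000223, at the preset correlation, so it does not measure the spread between arrays alone. Between arrays, the list mean had SDs of 0.153 and 0.087 with serine (compound and DMSO) and 0.012 and 0.129 without. Dim probe sets are argued against (camera adjusted p = 2.46e-06 among members above the 40th percentile, at the same preset). The pattern may be biological, as a hypothesis found and tested on the same arrays; with serine the list itself did not pass (median 0.17, camera adjusted p = 0.121), and a difference between cultures was not tested.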

How the results depend on the processing

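Of the alternatives counted here, the leave-outs of the interferon list at 24 h were chosen after the data were seen. Counts of called genes were within 1.5 times of the reported ones except as follows, and the cause was not tested where none is given. Fitting only the arrays of the comparison leaves few degrees of freedom and uses the spread of those arrays alone. Which of these lowered the counts was not tested. For compound 16 without serine they were 0, 89 and 440 at 1.5, 6 and 24 h (15, 496 and 1290 reported). With serine at 24 h the count was 24 (250). For the differences between media at 1.5, 6 and 24 h they were 0, 56 and 67 (3, 164 and 234). For serine lack at 0, 1.5, 6 and 24 h they were 6, 1, 25 and 0 (1075, 360, 580 and 29). For the change of medium with serine the count was 2518 (3968). Leaving out dim genes, so that fewer are tested, gave 2 for compound 16 with serine at 0 h (0) and 391 at 24 h, 7 for the difference at 1.5 h and 53 for serine lack at 24 h. A trended robust prior gave 1 with serine at 0 h, 8 for the difference at 1.5 h and 51 for serine lack at 24 h. Array weights gave 768 without serine at 6 h, 1 with serine at 1.5 h (0), 13 for the difference at 1.5 h and 631 for serine lack at 1.5 h. The mean of all probe sets gave 1 without and 2 with serine at 0 h and 56 for serine lack at 24 h. Median centring gave 1 for the difference at 0 h (0).

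Leaving out 1 array at a time, which leaves a group of 1 in the 1.5 h DMSO arrays with serine and assumes that array varies like the others, gave for compound 16 without serine 0 to 6, 6 to 8, 307 to 348 and 978 to 1060 genes at 0, 1.5, 6 and 24 h. With serine it gave 0 to 2, 0 to 0, 0 to 1 and 128 to 219, for the differences 0 to 0, 1 to 4, 116 to 158 and 158 to 215, for serine lack 694 to 868, 85 to 257, 305 to 456 and 9 to 41, and for the change of medium 3291 to 3517 with and 4545 to 4759 without serine. Beside those named in the report, the arrays that moved a count by over 1.5 times were plusSer_0h_C16 replicate 12 (2) and plusSer_0h_DMSO replicate 15 (1), plusSer_6h_C16 replicate 58 (1), for serine lack at 0 h plusSer_0h_DMSO replicates 13 and 14 (694 and 708) and minusSer_0h_DMSO replicates 19 and 21 (700 and 711), and at 24 h plusSer_24h_DMSO replicate 98 (9) and each of the 3 minusSer_24h_DMSO arrays (11, 17 and 15 in the order of their numbers).

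Of the named gene results, 1 reversed: RFC4 under serine lack at 0 h was 0.033 with the mean of all probe sets (-0.26 reported). Values of named genes lost their call in 653 settings, 340 of them leave-outs and 228 fits of only the arrays of the comparison, and gained it in 70. A further 115 settings turned the sign of a value that passed no test in either. Called lists reversed in 0 settings and lost their call in 26, of which 13 with an estimated correlation, 6 with dim genes left out, 4 with the mean of all probe sets, 2 under quantile normalization and 1 under median centring. The losses other than by an estimated correlation were of NRF2 targets under compound 16 without serine at 24 h (dim genes), the ER unfolded protein response there and under serine lack at 1.5 h (mean of probe sets), p53 targets (dim genes, mean of probe sets) and ribosome biogenesis (dim genes, quantile) under serine lack at 6 h, and for the change of medium the ER unfolded protein response with serine (dim genes, centring, mean of probe sets) and, without it, the amino acid response (dim genes) and purine synthesis (dim genes, quantile). Lists were not run with only the arrays of the comparison, nor with arrays left out except for the interferon list at 24 h, and the trended robust prior does not enter camera, so the stability of list calls under these settings is not known. No paired analysis was possible because no groups share replicate numbers. Scaling moved the median of all genes by less than 0.1 in each comparison. Signal over background was not assessed, and with 3 arrays per group and a median SE of 0.122, changes well under 0.5 on the log2 scale were often not detectable.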

Other observations

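Comparisons over time in DMSO were added after the data were seen, and in all of them array block and time coincide. From 6 h to 24 h in DMSO with serine, 14 of 19 ribosome biogenesis genes fell (median -0.43, camera adjusted p = 3.99e-16), as did 18 of 23 S phase genes (median -0.44), and 2 of the 3 glucose-sensing genes rose, with TXNIP at 1.81 ± 0.23. Without serine over the same interval, ribosome biogenesis and S phase genes fell as well, in 10 of 19 and 9 of 23 genes (medians -0.23 and -0.23), and TXNIP rose by 1.21 ± 0.23. The change without serine minus that with serine had a median of 0.09 for ribosome biogenesis (0 of 19 past the test, camera adjusted p = 0.00245). It was 0.21 for S phase (1 of 23 higher, camera adjusted p = 1.44e-10). For mitosis genes it was 0.28 (4 of 23 higher, camera adjusted p = 4.66e-22). With an estimated correlation these camera adjusted p-values were 0.00278, 4.05e-05 and 5.77e-08. Without serine, 20 of 23 mitosis genes rose (median 0.36, camera adjusted p = 2.61e-26), with KIF20A at 0.65 ± 0.07, while 13 of 19 amino acid response genes and 12 of 19 aminoacyl-tRNA synthetases fell (medians -0.64 and -0.32), and 9 of 18 genes of the ER unfolded protein response fell and 1 rose (median -0.23).

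From 0 h to 1.5 h in DMSO without serine, CHAC1, a glutathione-degrading enzyme of the amino acid response, rose by 1.58 ± 0.16, DDIT3 by 1.05 ± 0.19 and EGR1 by 1.10 ± 0.21, and 9 of 19 amino acid response genes rose (median 0.16). With serine (n = 2 at 1.5 h) CHAC1 stood at -0.24 ± 0.18, DDIT3 at -0.61 ± 0.22 and EGR1 at 0.43 ± 0.24, none of them past the test. From 0 h to 6 h the amino acid response fell with serine (13 of 19 lower and 1 higher, median -0.45) and rose without it (11 higher and 2 lower, median 0.34). The mean signal of the list under compound 16 without serine was 9.07 at 1.5 h, 9.64 at 6 h and 9.07 at 24 h, and in DMSO without serine 8.75, 8.67 and 8.03, so the difference at 24 h was formed with a lower DMSO level than at 6 h.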
